A study of Chionodraco hamatus and Gymnodraco acuticeps and Trematomus bernacchii with 9 samples.

How the data were processed

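Bulk RNA of the head kidney was measured in 9 libraries, 3 each of C. hamatus, G. acuticeps and T. bernacchii. Per the labels' protocols, tissue was frozen, RNA was taken with Trizol, and libraries were made from total RNA with an Illumina TruSeq kit. The deposited file holds read counts, 1 whole number per row and library, with no normalization applied. The aligner, the reference and the counting tool are not given in the sources used here. Each of the 12653 rows is a UniProt entry name, a mnemonic with an organism code, and 11291 mnemonics are distinct. No genome was used, so no coordinates are given. Rows of 1 protein from several organisms, and members of gene families, may share reads, and each such row is uncertain.

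Total counts per library ran from 2501922 to 12055675. A floor of 3 counts per library corresponds to a mean of 0.769 CPM in C. hamatus, 0.664 in G. acuticeps and 0.683 in T. bernacchii. Where all libraries of a species were at 0, the fold is given as a lower bound against this floor. Where a species held 1 to 3 counts in all, the ratio of depth-scaled counts is given with its exact 95% binomial interval. Floors and intervals cover counting error only.

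Groups were the 3 species as labelled. Counts were filtered with filterByExpr, which left 8662 rows, scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, 1 estimate of the spread over all 9 libraries). Contrasts were each pair of species and C. hamatus minus the log-scale mean of the others. A row was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its absolute value over the square root of the quasi-likelihood F statistic. It is thus derived from the test and is approximate, above all for rows near 0. Rows that differed the same way are those called in both C. hamatus pairs with the same sign. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 25 lists with at least 5 tested members, and with an estimated correlation and fry. Figures were drawn with matplotlib 3.10.9.

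The comparisons, tests, gene symbols of the lists, alternatives and the rule for named genes were chosen before the data were examined, apart from the additions stated. The lists cover globins, heme synthesis, iron handling, erythroid regulators, red cell membrane, TGF-beta and BMP signalling, cell cycle, apoptosis, antioxidants, hypoxia and vessel growth, neutrophils, macrophages, B cells, T cells, thrombocytes, stem and progenitor cells, kidney tubule and glomerulus, interrenal and chromaffin cells, stroma and vessels, skeletal muscle, the respiratory chain, ribosomal proteins, the proteasome, and heat shock proteins. Their gene symbols were translated by hand to UniProt mnemonics after the row names were seen, with exact matching in place of the planned suffix rule, which hit unrelated proteins. Some rows that the lists could hold were not analysed here. Named genes were the 12 highest and 12 lowest of the rows that differed the same way, up to 4 members per list with the largest absolute change among those called, any tested member of the TGF-beta, erythroid, globin and heme lists, and the 6 highest and 6 lowest of each pair, each with a mean count of at least 100 in the higher species outside the lists.

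The fit was tested on simulated counts for the 8662 rows with 200 rows changed. Against G. acuticeps, it recovered 2% of rows changed 2-fold, 10% at 4-fold, 90% at 16-fold and 96% at 64-fold. Against T. bernacchii the shares were 2%, 8%, 92% and 96%, and against the mean of both 4%, 26%, 94% and 98%. Unchanged rows called numbered 3, 1 and 2. Far fewer rows were changed than were called in the data, so the adjusted threshold was stricter in the simulation and these shares do not carry over. The sizes 16 and 64 were added after the recovery at 2 and 4 was seen. In 20 simulations with no difference between any of the species, a mean of 0.05 rows and at most 1 differed the same way. With no difference built in, a count near 0 was fixed in advance. It is no baseline for the rows that differed the same way in the data.

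Alternatives were DESeq2 1.42.0 (its size factors in edgeR, and its own test), upper-quartile factors, no filter, a filter of at least 50 counts in 3 libraries, a replicate block, glmTreat against a fold of 2, leaving out the 20 highest rows, fitting only the 6 libraries of a pair, and leaving out each library in turn. Added after seeing the data were rows counted in every species, rows of 1 mnemonic summed, and leaving out C. hamatus replicates 2 and 3. Intervals of list medians come from 10000 bootstrap draws over members at 95%.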

Results

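The series compared the head kidney, the main blood-forming organ of bony fish, of 3 notothenioid species from Antarctic waters. Chionodraco hamatus is an icefish, of a fish family that lacks hemoglobin, while Gymnodraco acuticeps and Trematomus bernacchii have red blood. The series title asks about suppressed red blood cell formation and TGF-beta signalling in the icefish. Each species had 3 libraries of bulk RNA, with total counts from 2501922 to 12055675 per library. The C. hamatus libraries held 5172770, 2501922 and 4294414 counts, the G. acuticeps libraries 3052436, 4310369 and 12055675, and the T. bernacchii libraries 3867403, 2600100 and 11861252. The deposited table has 12653 rows, each a protein entry of some organism in UniProt, so a row is named below by its entry name, such as HEM0_OPSTA. Of these rows, 8662 passed the filter on low counts and were tested. Spearman correlations across genes ran from 0.844 to 0.910 between C. hamatus libraries, 0.944 to 0.963 within G. acuticeps, 0.879 to 0.921 within T. bernacchii and 0.604 to 0.741 between species. Nothing in the labels says that the libraries came from separate animals, so the p-values measure only the spread between these samples. Values per gene are means of TMM-scaled CPM, the usual depth-scaled counts, ± SD over n = 3 libraries, and every adjusted p of a gene comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

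The C. hamatus libraries differed in transcripts of adrenal cell types, which lie within the head kidney of fish as steroid-making interrenal cells and catecholamine-making chromaffin cells. The summed CPM of the interrenal list was 10517 in C. hamatus replicate 3, against 51.9 and 129.6 in replicates 1 and 2, and 123 to 215 in G. acuticeps and 30.7 to 54.8 in T. bernacchii. STAR_SALFO, the cholesterol carrier that starts steroid synthesis, was the highest row of C. hamatus replicate 3 with 1.89% of its counts. The chromaffin sum was 9220.0 in C. hamatus replicate 2 and 4292 in replicate 3, against 52.2 in replicate 1, the lowest of all 9 libraries. It was 143 to 206 in G. acuticeps and 539, 88.8 and 531 in T. bernacchii, so such transcripts were not limited to C. hamatus. Of the interrenal list, 4 of 5 tested members were higher and 0 lower (4 and 0 adjusted over the list alone), with a median log2 fold change of 4.90 against the mean of the other species, and camera's adjusted p was 0.470. Higher ones numbered 1 without C. hamatus replicate 3. Of the chromaffin list, 7 of 11 tested members were higher and 1 lower (8 and 1 adjusted over the list alone), with a median of 4.87 (4.82 with members at 0 set to their bound) and an adjusted p of 0.481, or 0.00595 without C. hamatus replicate 1. Higher ones numbered 4 without C. hamatus replicate 2. CP11A_ONCMY, the cholesterol side-chain cleavage enzyme, had a log2 fold change of 5.99 (SE 1.45) with all libraries and -1.13 without C. hamatus replicate 3. CP17A_ICTPU, a steroid hydroxylase, had 8.12 (SE 1.88), and 1.63 without that library, 8.71 without C. hamatus replicate 1, 9.11 without G. acuticeps replicate 1 and 9.44 without T. bernacchii replicate 3; by counts it was 1057-fold (95% counting interval 361 to 5128) over T. bernacchii. NCPR_BOVIN, the reductase that supplies such enzymes with electrons, had 4.90 (SE 1.18), and 0.78 (adjusted p = 0.434) without C. hamatus replicate 3, 5.49 without C. hamatus replicate 1 and 5.65 without T. bernacchii replicate 2. TY3H_ANGAN, the tyrosine hydroxylase of catecholamine synthesis, had 5.21 (SE 1.54), and 3.08 without C. hamatus replicate 2. Its call was also lost without G. acuticeps replicate 1 (4.99, adjusted p = 0.0527) or 2 (4.93, adjusted p = 0.0517), in a range of 0.00457 to 0.246 over its alternatives, and its value was 7.46 without G. acuticeps replicate 3. PNMT_PIG, which makes adrenaline, had 6.85 (SE 1.69), and the values without 1 library ran from 4.50 to 7.39, lowest without C. hamatus replicate 2; against T. bernacchii alone neither it (adjusted p = 0.126) nor TY3H_ANGAN (0.295) was called. With a replicate block in the model the calls of CP11A_ONCMY (2.78, adjusted p = 0.412), NCPR_BOVIN (3.49, 0.157), TY3H_ANGAN (4.49, 0.162) and PNMT_PIG (6.80, 0.0700) were lost. The muscle list summed to 22793 to 38339.7 CPM in G. acuticeps, 936 to 1396 in C. hamatus and 764 to 4295 in T. bernacchii. The skeletal muscle actin row ACTS_ORYLA held 61156, 122853 and 293856 counts in G. acuticeps and 74 to 489 in T. bernacchii. ACTB_OREMO, another actin, held 503 to 3739 and 71553 to 201006. The 6 actin rows counted here together held 2.49% of the counts in G. acuticeps and 2.20% in T. bernacchii. In C. hamatus they held only 0.0994% ± 0.114 (SD, n = 3), and whether its actin reads lay on other rows was not tested. The muscle sum may partly reflect which actin row took the reads, which was not tested.

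**Figure D1:**
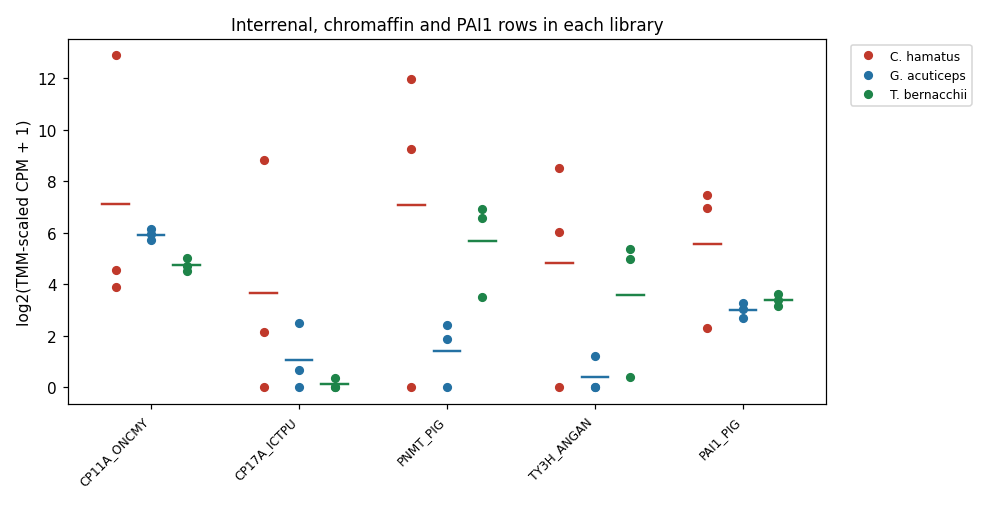
TMM-scaled CPM of 5 rows on a log2 scale (plus 1), by species. Each point is 1 library and each bar the mean of its group on that scale. CP11A_ONCMY is far higher in C. hamatus replicate 3 than in the other libraries, and PNMT_PIG is high in C. hamatus replicates 2 and 3 and 0 in replicate 1.

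The comparison of C. hamatus with both red-blooded species asks what sets the icefish apart. Some genes of red blood cells were far lower in C. hamatus. The erythroid form of the first enzyme of heme synthesis, HEM0_OPSTA, stood at 9.76 ± 2.43 CPM in C. hamatus against 2707 ± 232 in G. acuticeps and 873 ± 319 in T. bernacchii. TAL1_TAKRU, a transcription factor that blood cell formation requires, stood at 0.442 ± 0.465, 432 ± 287 and 63.95 ± 21.6 CPM. Of 59 tested rows of TGF-beta and BMP signalling, 28 were higher in C. hamatus, with BMP7_MOUSE at 124 ± 70.9 CPM and at 0 in all 6 other libraries. Camera placed the stroma and vessel list higher and the cell-cycle list lower, and neither call held with an estimated correlation (adjusted p = 0.523 and 0.444). Against the mean of the other species, 3535 of 8662 rows differed, 2296 higher and 1239 lower in C. hamatus, and 1559 differed the same way from each of the other species, 877 higher and 682 lower. More higher than lower rows the same way were not seen with a filter of at least 50 counts in 3 libraries, 566 each way, and the sides were close without C. hamatus replicate 3, 785 and 749. If both contrasts were independent, 384 higher and 216 lower rows would be shared. Both use the same C. hamatus libraries, so they are not independent and these values are no baseline. A further 98 and 58 rows went opposite ways. Of the 1559 rows, 30.7% were at 0 in all libraries of a species. The rows are entries of many organisms, so a row at 0 does not show that the gene is silent in that fish. Without C. hamatus replicates 2 and 3, the libraries with the most adrenal transcripts, 2041 rows differed from the mean and 875 the same way, 376 higher and 499 lower.

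Hemoglobin rows were nearly empty in C. hamatus. All 7 globin rows together held 0 to 3 counts in each C. hamatus library, 1.81% ± 0.157 (SD, n = 3) of the counts in G. acuticeps and 11.3% ± 3.71 in T. bernacchii. HBAD_APUAP, an alpha-type globin counted in both red-blooded species, was at least 143-fold lower in C. hamatus than in G. acuticeps and at least 80.2-fold lower than in T. bernacchii, against a floor of 3 counts per library. Most other globin reads fell on different rows in the 2 red-blooded species, so against their mean 0 of 6 tested members were higher and 2 lower (0 and 2 adjusted over the list alone), with a median of -10.25 (-7.10 with members at 0 set to their bound), and camera's adjusted p was 0.172, in a range of 0.000213 to 0.523 over its alternatives. HBA2_GOBGI, 1 of the 2 lower rows, has a single count in T. bernacchii, and without that library, T. bernacchii replicate 3, its call was lost (adjusted p = 0.9998) and 1 was left. Heme synthesis genes went the same way: of the list, 1 of 15 tested members were higher and 10 lower (1 and 11 adjusted over the list alone), with a median of -2.66 and camera's adjusted p = 4.84e-05, or adjusted p = 0.0655 with an estimated correlation. HEM0_OPSTA was lower (log2 fold change -7.29, SE 0.53, adjusted p = 5.86e-05). The mitochondrial iron carrier MFRN1_DANRE, with 2 counts in C. hamatus, was lower there than in G. acuticeps by counts, 1205-fold (95% counting interval 333 to 9953), and than in T. bernacchii, 99.3-fold (95% counting interval 27.2 to 824). TM14C_DANRE, a heme-precursor transporter, had a log2 fold change of -3.86 (SE 0.64) and coproporphyrinogen oxidase HEM6_HUMAN -3.30 (SE 0.44); the highest adjusted p among these was 0.00104. HEM1_OPSTA, the form of the first heme enzyme that most tissues use, was higher (log2 fold change 1.40, SE 0.46, adjusted p = 0.0344), and its call was kept only without C. hamatus replicate 1, G. acuticeps replicate 3 or T. bernacchii replicate 2; without each other library the adjusted p rose, up to 0.142, and without C. hamatus replicates 2 and 3 the log2 fold change was 0.02. It was called against neither species alone (adjusted p = 0.0543 and 0.106). Over its alternatives the adjusted p ran from 0.00982 to 0.9999.

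Camera placed regulators of red cell formation lower, as a list. Of this list, 0 of 19 tested members were higher and 7 lower (0 and 7 adjusted over the list alone), with a median of -0.96 and camera's adjusted p = 0.00332, or adjusted p = 0.425 with an estimated correlation. TAL1_TAKRU was lower (log2 fold change -8.38, SE 0.88, adjusted p = 0.000132), and -9.31 without C. hamatus replicate 1. KLF1_HUMAN, a transcription factor of red cell and globin genes, had a log2 fold change of -5.48 (SE 0.69), the heme-regulated kinase E2AK1_MACFA -5.28 (SE 0.91), or -7.08 without C. hamatus replicate 3, and the TAL1 partner RBTN2_DANRE -3.71 (SE 0.46), with adjusted p up to 0.00120. NFE2_BOVIN, an activator of globin genes, differed from T. bernacchii alone: it stood at 5.16 ± 2.06 CPM in C. hamatus, 8.77 ± 3.73 in G. acuticeps and 319.6 ± 143 in T. bernacchii (adjusted p = 0.247 against G. acuticeps and 0.000173 against T. bernacchii). The erythropoietin receptor EPOR_PIG was not called (log2 fold change -0.88, SE 0.71, adjusted p = 0.354). Red cell membrane and enzyme genes went both ways: 8 of 26 tested members were higher and 11 lower (8 and 11 adjusted over the list alone), with a median of -0.18 (-0.25 with members at 0 set to their bound) and camera's adjusted p = 0.141, or 0.0448 without G. acuticeps replicate 3. Among the lower ones, the Rh-associated protein RHAG_HUMAN had a log2 fold change of -6.30 (SE 0.87), or -7.21 without C. hamatus replicate 2, the red cell carbonic anhydrase CAHZ_DANRE -6.02 (SE 0.61) and the erythroid surface protein ERMAP_HUMAN -3.80 (SE 0.46), with adjusted p up to 0.000377. Band 3, the anion exchanger B3AT_ONCMY, was lower (log2 fold change -2.66, SE 0.64, adjusted p = 0.00779), and was no longer called without C. hamatus replicates 2 and 3 (-3.11, adjusted p = 0.0803, in a range of 5.84e-05 to 0.0803 over its alternatives). Its C. hamatus values, 164 to 299.8 CPM, overlapped those of T. bernacchii, 210.1 to 565, and lay below those of G. acuticeps, 1541 to 9508; against T. bernacchii alone it was not called (adjusted p = 0.393). RHBG_TAKRU, an ammonia transporter, was higher (adjusted p = 0.000172), by counts 707-fold (95% counting interval 126 to 27980) over G. acuticeps and 359-fold (95% counting interval 98.9 to 2973) over T. bernacchii. Iron handling genes split, with 6 of 19 tested members higher and 6 lower (6 and 6 adjusted over the list alone); the median was 0.62, the mean 0.0094 and camera's direction down (adjusted p = 0.818). NRAM2_MOUSE, an iron importer, had a log2 fold change of 5.33 (SE 0.63), adjusted p = 0.000194.

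**Figure D2:**
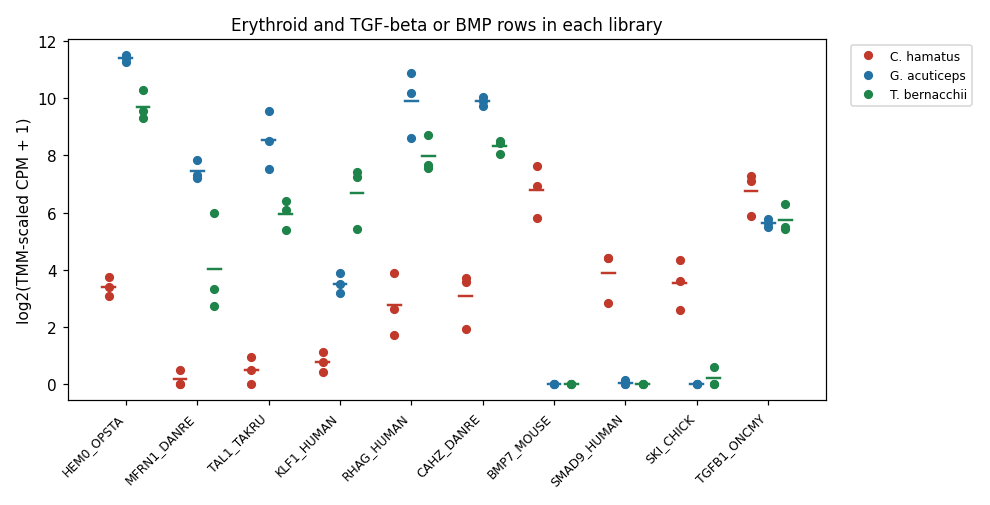
TMM-scaled CPM of 10 rows on a log2 scale (plus 1), by species. Each point is 1 library and each bar the mean of its group on that scale. The 6 erythroid rows at left are lower in every C. hamatus library than in any other, and BMP7_MOUSE, SMAD9_HUMAN and SKI_CHICK are near 0 outside C. hamatus.

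TGF-beta and BMP signalling genes that differed were more often higher than lower in C. hamatus. Of this list, 28 of 59 tested members were higher and 3 lower (28 and 3 adjusted over the list alone), with a median of 1.30. Camera's adjusted p was 0.0516, just short of the threshold, and adjusted p = 0.634 with an estimated correlation. Without any 1 library other than C. hamatus replicate 2, camera's adjusted p was 0.0120 to 0.0472, and 0.0921 without that one. The ligand BMP7_MOUSE was higher in C. hamatus, at least 187-fold over G. acuticeps and at least 182-fold over T. bernacchii. The BMP signal carrier SMAD9_HUMAN was 286-fold (95% counting interval 50.8 to 11366) over G. acuticeps by counts and at least 22.7-fold over T. bernacchii. SKI_CHICK, a repressor of SMAD signalling, was at least 17.9-fold over G. acuticeps and by counts 113-fold (95% counting interval 30.8 to 942) over T. bernacchii. The TGF-beta signal carrier SMAD2_DANRE had a log2 fold change of 6.32 (SE 0.84), or 7.22 without T. bernacchii replicate 2, and the shared partner SMAD4_HUMAN 3.37 (SE 0.55), or 2.51 without C. hamatus replicate 3, with an adjusted p of at most 0.00124 for these 4. The BMP receptor BMR1B_HUMAN was higher (log2 fold change 3.48, SE 0.52, adjusted p = 0.000586), 2.64 without C. hamatus replicate 2, but not called without C. hamatus replicates 2 and 3 (1.91, adjusted p = 0.0578, in a range of 5.40e-08 to 0.0578 over its alternatives). TGFB1_ONCMY, the ligand TGF-beta 1, was higher (log2 fold change 1.17, SE 0.38, adjusted p = 0.0301), a call kept only when the library left out was C. hamatus replicate 3 or T. bernacchii replicate 2; without each other one the adjusted p was up to 0.127, and over all its alternatives it ran from 0.00715 to 0.127, with 0.0511 with no filter. It was not called against T. bernacchii alone (adjusted p = 0.0910), nor was TGFB3_HUMAN (adjusted p = 0.109). TGFB3_HUMAN had 3.75 (SE 1.07) with all libraries and 0.70 (adjusted p = 0.600) without C. hamatus replicate 3, and 4.37 without T. bernacchii replicate 2; its adjusted p was 0.160 with a replicate block and 0.00981 to 0.755 over its alternatives. PAI1_PIG, a classical TGF-beta target, had 3.60 (SE 0.76), 2.92 without C. hamatus replicate 3, and -1.06 without C. hamatus replicates 2 and 3. Lower rows included the coactivator CBP_RAT (log2 fold change -6.89, SE 0.87, adjusted p = 0.000259; -8.10 without C. hamatus replicate 1 and -6.24 without C. hamatus replicate 3) and the BMP target ID3A_XENLA (log2 fold change -3.54, SE 0.49, adjusted p = 0.000397). The receptor TGFR2_CHICK was not called (log2 fold change -0.43, SE 0.43, adjusted p = 0.453). In the stroma and vessel list, 17 of 29 tested members were higher and 1 lower (18 and 2 adjusted over the list alone), with a median of 1.67.

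Stroma and vessel genes were higher in C. hamatus by camera (adjusted p = 0.0103, or adjusted p = 0.523 with an estimated correlation). CO6A1_MOUSE, a collagen VI chain, stood at 701 ± 181 CPM in C. hamatus and 15.2 ± 5.93 in G. acuticeps, and was at least 1026-fold over T. bernacchii. CO6A3_CHICK, another chain of collagen VI, was lower (log2 fold change -7.61, SE 0.90, adjusted p = 0.000197), and all of its 6 C. hamatus counts lay in replicate 3. Camera placed hypoxia and vessel-growth genes higher too: 9 of 22 tested members were higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 1.08 and camera's adjusted p = 0.0279, or adjusted p = 0.523 with an estimated correlation and 0.0921 without C. hamatus replicate 2. BNIP3_HUMAN, a hypoxia-induced mitophagy protein, was at least 85.3-fold over G. acuticeps and at least 83.0-fold over T. bernacchii. The vessel growth factor VEGFA_MOUSE was higher (log2 fold change 5.75, SE 1.09, adjusted p = 0.00211), but 3.55 without C. hamatus replicate 2 and 2.05 (adjusted p = 0.313, in a range of 1.03e-06 to 0.313 over its alternatives) without C. hamatus replicates 2 and 3. The VEGF receptor VGFR4_DANRE was higher (log2 fold change 7.58, SE 1.01, adjusted p = 0.000324), and 6.59 without C. hamatus replicate 3, 9.15 without G. acuticeps replicate 3 and 9.03 without T. bernacchii replicate 3. Cell-cycle genes were lower, with 1 of 68 tested members higher and 38 lower (1 and 39 adjusted over the list alone), a median of -2.19 and camera's adjusted p = 2.17e-09, or adjusted p = 0.444 with an estimated correlation. MPIP1_HUMAN, a phosphatase that starts mitosis, stood at 5.26 ± 4.26, 341 ± 57.7 and 227 ± 15.3 CPM (log2 fold change -5.75, SE 0.60, adjusted p = 0.000128), with -6.62 without C. hamatus replicate 2. The summed cell-cycle CPM was 16034 in C. hamatus replicate 1 against 4793 and 6377 in replicates 2 and 3; it was 9277 to 15988 in T. bernacchii, all below C. hamatus replicate 1, and 20929.7 to 28275 in G. acuticeps.

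**Figure D3:**
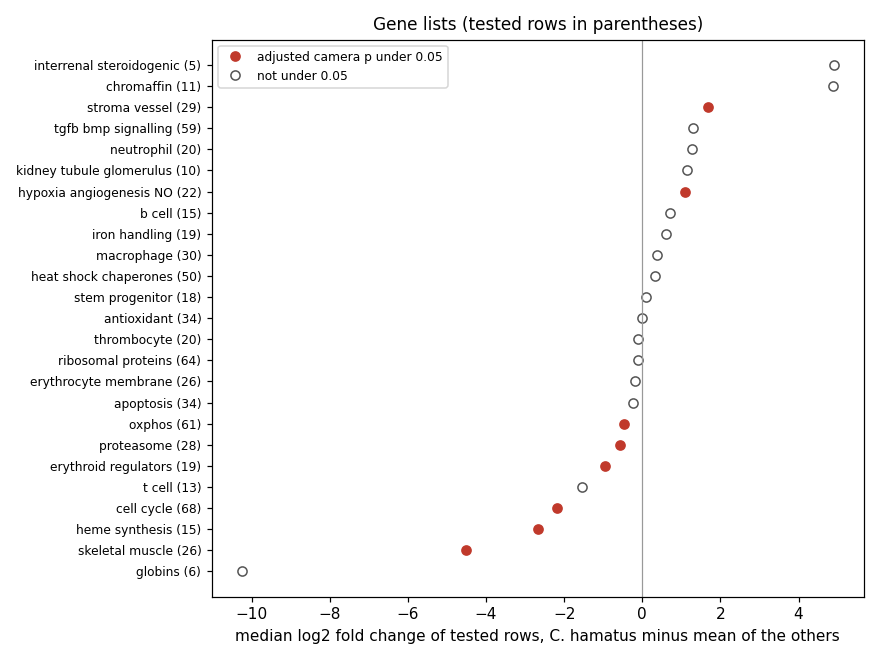
Median log2 fold change of the tested rows of each of 25 gene lists, C. hamatus minus the mean of the other species, with the number of tested rows in parentheses. Filled points are lists with an adjusted camera p under 0.05 at the preset correlation; none is under 0.05 with an estimated correlation. Globins have the lowest median and interrenal and chromaffin lists the highest.

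Skeletal muscle rows were lower in C. hamatus, with 2 of 26 tested members higher and 16 lower (2 and 16 adjusted over the list alone), a median of -4.50 and camera's adjusted p = 0.00318, or adjusted p = 0.634 with an estimated correlation. The sum of this list was high in G. acuticeps, where actin reads may have been assigned differently. The list was not called against T. bernacchii alone (camera's adjusted p = 0.0693). Higher ones numbered 4 without T. bernacchii replicate 2. CASQ1_RAT, the calcium store protein calsequestrin, went the other way, with 635 ± 373 CPM in C. hamatus and 0.511 ± 0.634 in G. acuticeps (adjusted p = 9.25e-05), and was at least 929-fold over T. bernacchii. Camera placed the respiratory chain list lower, though most members were not called: 6 of 61 tested members were higher and 10 lower (5 and 7 adjusted over the list alone), median -0.46, adjusted p = 0.0399, or adjusted p = 0.871 with an estimated correlation. Lower ones numbered 4 without C. hamatus replicate 2 and 6 without C. hamatus replicate 1 or G. acuticeps replicate 2 or 3. The proteasome list was placed lower too, again with most members not called: 0 of 28 tested members were higher and 8 lower (0 and 1 adjusted over the list alone), median -0.57, adjusted p = 0.0310, or adjusted p = 0.854 with an estimated correlation. Lower ones numbered 2 without C. hamatus replicate 2 or 3 or G. acuticeps replicate 2 or 3 or T. bernacchii replicate 3 and 4 without T. bernacchii replicate 1. Without C. hamatus replicate 2 the adjusted p of these lists was 0.160 and 0.0727; it was 0.108 for the proteasome without C. hamatus replicate 3 and 0.0581 for the respiratory chain without G. acuticeps replicate 3. Ribosomal protein genes were not called as a list: 2 of 64 tested members were higher and 3 lower (2 and 3 adjusted over the list alone), median -0.12, adjusted p = 0.0751. Lower ones numbered 10 without C. hamatus replicate 1. That list passed without C. hamatus replicate 1 (adjusted p = 8.34e-05), G. acuticeps replicate 1 (0.00915) or 2 (0.0476), or T. bernacchii replicate 1 (0.0455) or 2 (0.0205).

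White blood cell and thrombocyte genes did not move together. The summed CPM of the neutrophil list was 9257 in C. hamatus replicate 2, against 4669.7 and 2829.9 in replicates 1 and 3, and 8009 in T. bernacchii replicate 2, against 3607 and 3425; it was 1836 to 2280.2 in G. acuticeps. The macrophage sum was also highest in these 2 libraries, 17922 and 13408, against 5238 and 10010.2 in the other C. hamatus libraries, 7672 and 8151 in the other T. bernacchii ones and 5845 to 8228 in G. acuticeps. For neutrophil genes, 9 of 20 tested members were higher and 3 lower (9 and 4 adjusted over the list alone), with a median of 1.27 (1.14 with members at 0 set to their bound) and adjusted p = 0.470. Higher ones numbered 4 without C. hamatus replicate 2 and 5 without G. acuticeps replicate 2. For macrophage genes, 5 of 30 tested members were higher and 5 lower (4 and 5 adjusted over the list alone), with a median of 0.37 and adjusted p = 0.771. Higher ones numbered 1 without C. hamatus replicate 2, 3 without G. acuticeps replicate 2 or 3, 8 without C. hamatus replicate 1 and 10 without T. bernacchii replicate 2, and lower ones numbered 3 without G. acuticeps replicate 2 or 3. For B cell genes, 4 of 15 tested members were higher and 1 lower (4 and 1 adjusted over the list alone), with a median of 0.70 (0.34 with members at 0 set to their bound) and adjusted p = 0.792. For T cell genes, 4 of 13 tested members were higher and 5 lower (4 and 5 adjusted over the list alone), with a median of -1.54 and adjusted p = 0.470. Lower ones numbered 3 without C. hamatus replicate 2 or G. acuticeps replicate 2. For thrombocyte genes, 5 of 20 tested members were higher and 5 lower (6 and 5 adjusted over the list alone), with a median of -0.10 and adjusted p = 0.792. For stem and progenitor genes, 8 of 18 tested members were higher and 5 lower (8 and 5 adjusted over the list alone), with a median of 0.11 and adjusted p = 0.470. Higher ones numbered 5 without C. hamatus replicate 2 or G. acuticeps replicate 1 or 3. Within these lists, the integrin chain ITB2_HUMAN of leukocytes was higher (log2 fold change 5.48, SE 0.97, adjusted p = 0.00139), 4.10 without C. hamatus replicate 2 and 6.75 without T. bernacchii replicate 2. The T cell kinase LCK_CHICK was higher (log2 fold change 6.05, SE 0.52, adjusted p = 8.29e-05), 6.66 without G. acuticeps replicate 2, and HHEX_CHICK, a blood progenitor factor, was at least 73.4-fold lower than in G. acuticeps and at least 38.9-fold lower than in T. bernacchii. The other lists were not called either. For kidney tubule and glomerulus genes, 4 of 10 tested members were higher and 1 lower (4 and 2 adjusted over the list alone), with a median of 1.14 and adjusted p = 0.470. Higher ones numbered 8 without C. hamatus replicate 1. For apoptosis genes, 6 of 34 tested members were higher and 6 lower (5 and 6 adjusted over the list alone), with a median of -0.24 and adjusted p = 0.470. For antioxidant genes, 9 of 34 tested members were higher and 7 lower (9 and 7 adjusted over the list alone), with a median of -0.01 and adjusted p = 0.382. For heat shock and chaperone genes, 10 of 50 tested members were higher and 6 lower (10 and 6 adjusted over the list alone), with a median of 0.34 and adjusted p = 0.792. Higher ones numbered 5 without C. hamatus replicate 2 and 16 without T. bernacchii replicate 2. Camera's direction was down for macrophage and heat shock genes, whose median and mean were above 0, and for stem and progenitor genes, whose median was above 0 and mean below. For thrombocyte genes the median was below 0, the mean above and camera's direction down. Catalase, CATA_DANRE, was at least 419-fold lower in C. hamatus than in G. acuticeps and at least 181-fold lower than in T. bernacchii, or 89.5-fold without T. bernacchii replicate 2.

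The 12 rows with the largest rise over both other species included IGKC_MOUSE, NATTL_DANRE, INSM2_HUMAN and BRD7_CHICK. IGKC_MOUSE, an immunoglobulin kappa constant region, stood at 26301 ± 17918 CPM in C. hamatus, 57.3 ± 81.1 in G. acuticeps and 0 in T. bernacchii, at least 38518-fold over the last, or 23606-fold without C. hamatus replicate 1. T. bernacchii held kappa reads on another row, KV401_HUMAN, with 8.66% and 7.60% of the counts of replicates 1 and 3. The fold of IGKC_MOUSE may thus reflect which row took the reads. NATTL_DANRE, a natterin-like protein, was at least 455-fold over G. acuticeps and at least 443-fold over T. bernacchii. INSM2_HUMAN, a zinc-finger transcription factor, stood at 440.0 ± 139.5 CPM in C. hamatus and 0.0647 ± 0.112 in T. bernacchii, by counts 3801-fold (95% counting interval 1052 to 31394), and was at least 662-fold over G. acuticeps. BRD7_CHICK, a bromodomain protein, was at least 163-fold over G. acuticeps and at least 159-fold over T. bernacchii. Among the 12 lowest were ATF4_DANRE, a stress-response transcription factor, at least 1795-fold lower than in G. acuticeps and at least 695-fold lower than in T. bernacchii, or 379.8-fold without T. bernacchii replicate 2, and PAF1_DANRE, a transcription elongation factor, at least 247-fold and at least 633-fold lower. RL37_RAT, a ribosomal protein, stood at 0.265 ± 0.459 CPM in C. hamatus and 5563 ± 2364 in G. acuticeps (adjusted p = 7.76e-05), and all of its 4 C. hamatus counts lay in replicate 3. Its reads may have been assigned to another entry in C. hamatus, which was not tested. NUSAP_DANRE, a spindle protein, was at least 247-fold lower than in G. acuticeps and at least 173-fold lower than in T. bernacchii.

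Some globin and heme genes were lower in C. hamatus than in G. acuticeps, a red-blooded dragonfish, in the comparison that asks how these 2 species differ. HBA2_GOBGI, an alpha globin, stood at 8364 ± 934 CPM in G. acuticeps and at 0 in C. hamatus, at least 10879-fold lower. HBB2_PSEUR, a beta globin, stood at 11082 ± 770.4 and 0.493 ± 0.508 CPM (log2 fold change -14.56, SE 1.12, adjusted p = 8.81e-05; -15.50 without C. hamatus replicate 2 and -13.90 without C. hamatus replicate 3). Of 8662 rows, 3636 differed, 2177 higher and 1459 lower in C. hamatus, and without C. hamatus replicates 2 and 3 there were 2247. For globins, 0 of 6 tested members were higher and 3 lower (0 and 3 adjusted over the list alone), with a median of -6.07 (-3.47 with members at 0 set to their bound) and camera's adjusted p = 7.26e-05, or adjusted p = 0.0482 with an estimated correlation. For heme synthesis, 0 of 15 tested members were higher and 9 lower (1 and 12 adjusted over the list alone), with a median of -3.16 and camera's adjusted p = 2.72e-06, or adjusted p = 0.0365 with an estimated correlation. For erythroid regulators, 1 of 19 tested members were higher and 7 lower (1 and 7 adjusted over the list alone), with a median of -1.16 and camera's adjusted p = 0.0110, or adjusted p = 0.425 with an estimated correlation. For red cell membrane genes, 5 of 26 tested members were higher and 10 lower (5 and 11 adjusted over the list alone), with a median of -0.77 and camera's adjusted p = 0.0499, or adjusted p = 0.740 with an estimated correlation. For the cell cycle, 1 of 68 tested members were higher and 43 lower (2 and 45 adjusted over the list alone), with a median of -2.31 and camera's adjusted p = 1.16e-09, or adjusted p = 0.381 with an estimated correlation. For skeletal muscle, whose sum was high in G. acuticeps, 2 of 26 tested members were higher and 17 lower (2 and 19 adjusted over the list alone), with a median of -5.25 (-4.99 with members at 0 set to their bound) and camera's adjusted p = 0.00136, or adjusted p = 0.740 with an estimated correlation. For ribosomal proteins, 0 of 64 tested members were higher and 4 lower (0 and 2 adjusted over the list alone), with a median of -0.43 and camera's adjusted p = 0.0102, or adjusted p = 0.867 with an estimated correlation. Lower ones numbered 2 without G. acuticeps replicate 3 and 22 without C. hamatus replicate 1. For the proteasome, 0 of 28 tested members were higher and 14 lower (0 and 14 adjusted over the list alone), with a median of -1.04 and camera's adjusted p = 0.0110, or adjusted p = 0.740 with an estimated correlation. Lower ones numbered 4 without G. acuticeps replicate 2 or 3, 5 without C. hamatus replicate 2 and 7 without C. hamatus replicate 3. For hypoxia and vessel growth, 9 of 22 tested members were higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 1.01 and camera's adjusted p = 0.0295, or adjusted p = 0.425 with an estimated correlation. For TGF-beta and BMP signalling, not called, 28 of 59 tested members were higher and 6 lower (29 and 6 adjusted over the list alone), with a median of 1.25 and camera's adjusted p = 0.0820, or adjusted p = 0.740 with an estimated correlation. Higher ones numbered 18 without G. acuticeps replicate 2 or 3. That list passed at an adjusted p of 0.0471 without C. hamatus replicate 1, 0.0441 without C. hamatus replicate 3, 0.0402 without G. acuticeps replicate 1, 0.0449 without T. bernacchii replicate 1, 0.0439 without T. bernacchii replicate 2 and 0.0490 without T. bernacchii replicate 3. Calls of lists were lost for red cell membrane genes (adjusted p = 0.0682 without C. hamatus replicate 2 and 0.0610 without T. bernacchii replicate 2), ribosomal proteins (0.0682 without C. hamatus replicate 2 and 0.0587 without C. hamatus replicate 3) and hypoxia and vessel growth (0.0871 without C. hamatus replicate 2). Calls were gained for the respiratory chain (adjusted p = 0.0589 with all libraries, 0.0279 without C. hamatus replicate 3, 0.00425 without G. acuticeps replicate 1, 0.0366 without G. acuticeps replicate 2, 0.0423 without T. bernacchii replicate 1, 0.0331 without T. bernacchii replicate 2 and 0.0331 without T. bernacchii replicate 3) and for stroma and vessels (0.0589 with all, 0.0353 without G. acuticeps replicate 1, 0.0449 without T. bernacchii replicate 1, 0.0331 without T. bernacchii replicate 2 and 0.0331 without T. bernacchii replicate 3). They were also gained for neutrophil (0.105 with all, 0.0347 without C. hamatus replicate 3) and chromaffin genes (0.414 with all, 0.00705 without C. hamatus replicate 1). Among single genes, EPN2_HUMAN, an endocytosis adaptor, stood at 1349 ± 379.6 CPM in C. hamatus and 0.0837 ± 0.145 in G. acuticeps, by counts 23745-fold (95% counting interval 4261 to 937938) (adjusted p = 5.72e-05). CHIT1_HUMAN, a macrophage chitinase, was at least 444-fold higher in C. hamatus, or 274-fold without C. hamatus replicate 2. NINJ1_HUMAN, a membrane protein of cell lysis, was at least 2868-fold lower, and the deubiquitinase UBP12_BOVIN at least 1783-fold lower. ROA1_PANTR, an RNA-binding protein, was at least 1434-fold lower.

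Globins led the rows lower in C. hamatus than in T. bernacchii, the pair that asks how the icefish differs from a red-blooded fish of another family. HBA_TREBE, its alpha globin, stood at 65134 ± 26659 CPM there and at 0 in C. hamatus, at least 84712-fold lower, and the beta globin HBB_TREHA was at least 61489-fold lower, or 37904-fold without T. bernacchii replicate 3. Of 8662 rows, 2810 differed, 1527 higher and 1283 lower in C. hamatus. Without C. hamatus replicate 3, 1368 were higher and 1388 lower, and without C. hamatus replicates 2 and 3 there were 1780, 850 higher and 930 lower. For globins, 0 of 6 tested members were higher and 4 lower (1 and 4 adjusted over the list alone), with a median of -14.18 (-9.19 with members at 0 set to their bound) and camera's adjusted p = 1.72e-07, or adjusted p = 0.0284 with an estimated correlation. For heme synthesis, 0 of 15 tested members were higher and 8 lower (0 and 10 adjusted over the list alone), with a median of -1.67 and camera's adjusted p = 0.00329, or adjusted p = 0.114 with an estimated correlation. For erythroid regulators, 1 of 19 tested members were higher and 7 lower (1 and 7 adjusted over the list alone), with a median of -1.35 and camera's adjusted p = 0.0190, or adjusted p = 0.459 with an estimated correlation. That list lost its call at an adjusted p of 0.0576 without T. bernacchii replicate 2. For the cell cycle, 2 of 68 tested members were higher and 26 lower (2 and 33 adjusted over the list alone), with a median of -1.77 and camera's adjusted p = 3.92e-06, or adjusted p = 0.459 with an estimated correlation. Lower ones numbered 15 without G. acuticeps replicate 2 or T. bernacchii replicate 1 or 3, 16 without C. hamatus replicate 2 or G. acuticeps replicate 3 and 17 without G. acuticeps replicate 1. For stroma and vessels, 14 of 29 tested members were higher and 1 lower (14 and 3 adjusted over the list alone), with a median of 1.48 and camera's adjusted p = 0.00462, or adjusted p = 0.459 with an estimated correlation. For TGF-beta and BMP signalling, not called, 16 of 59 tested members were higher and 5 lower (17 and 6 adjusted over the list alone), with a median of 1.16 and camera's adjusted p = 0.0822, or adjusted p = 0.761 with an estimated correlation. Higher ones numbered 27 without T. bernacchii replicate 2. That list passed at an adjusted p of 0.0422 without C. hamatus replicate 3 and 0.0424 without T. bernacchii replicate 2, and the respiratory chain, at 0.0822 with all libraries, at 0.0313 without C. hamatus replicate 3 and 0.0477 without T. bernacchii replicate 2. For skeletal muscle, not called, 4 of 26 tested members were higher and 13 lower (4 and 14 adjusted over the list alone), with a median of -3.85 and camera's adjusted p = 0.0693, or adjusted p = 0.861 with an estimated correlation. Higher ones numbered 1 without T. bernacchii replicate 1 and 2 without C. hamatus replicate 2 or T. bernacchii replicate 3, and lower ones numbered 8 without C. hamatus replicate 1. That one passed at an adjusted p of 0.0471 without C. hamatus replicate 2, 0.0431 without G. acuticeps replicate 1, 0.0201 without G. acuticeps replicate 2, 0.0217 without G. acuticeps replicate 3, 0.00628 without T. bernacchii replicate 1 and 0.0343 without T. bernacchii replicate 3. FIBB_HUMAN, the fibrinogen beta chain of clotting, was at least 1634-fold lower in C. hamatus, or 1042-fold without T. bernacchii replicate 3. The matrix protease MMP9_MOUSE was at least 956-fold lower, or 91.7-fold without T. bernacchii replicate 2. Higher rows included LAC6_HUMAN, an immunoglobulin lambda constant region, at least 7687-fold higher, or 3335-fold without C. hamatus replicate 1, and SC61G_XENLA, part of the protein channel of the endoplasmic reticulum, at least 613-fold higher.

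Globin rows and hepcidin differed between G. acuticeps and T. bernacchii, the pair that asks how far 2 red-blooded species differ. Their globin reads fell on different rows: HBB2_PSEUR was at least 16229.6-fold higher in G. acuticeps, and HBA_TREBE at least 98051-fold lower. HEPC_MORCS, the iron hormone hepcidin, stood at 2654 ± 1526 CPM in G. acuticeps and 0.0323 ± 0.0560 in T. bernacchii, by counts 55073-fold (95% counting interval 9884 to 2175294) (adjusted p = 0.000125). IFI27_HUMAN, an interferon-induced protein, was at least 1162-fold higher in G. acuticeps, and the adhesion molecule MUC18_HUMAN at least 1043-fold higher. Of 8662 rows, 2721 differed, 1138 higher and 1583 lower in G. acuticeps. For neutrophil genes, 1 of 20 tested members were higher and 14 lower (2 and 14 adjusted over the list alone), with a median of -3.78 (-3.12 with members at 0 set to their bound) and camera's adjusted p = 0.0294, or adjusted p = 0.856 with an estimated correlation. Lower ones numbered 5 without G. acuticeps replicate 1, 2 or 3 and 9 without T. bernacchii replicate 2. The summed CPM of this list was 8009 in T. bernacchii replicate 2, which stood apart from 3607 and 3425 in the other 2. For ribosomal proteins, 4 of 64 tested members were higher and 0 lower (2 and 0 adjusted over the list alone), with a median of 0.80 and camera's adjusted p = 0.0170, or adjusted p = 0.856 with an estimated correlation. Higher ones numbered 2 without G. acuticeps replicate 1, 2 or 3 or T. bernacchii replicate 1 or 2 and 8 without C. hamatus replicate 1. The neutrophil call was lost without G. acuticeps replicate 3 or T. bernacchii replicate 2 (adjusted p = 0.0567 and 0.0644), and the ribosomal one likewise (0.0847 and 0.0949). Of 2 red cell genes, which went opposite ways, HEM0_OPSTA was higher in G. acuticeps (log2 fold change 1.63, SE 0.42, adjusted p = 0.0140; adjusted p = 0.0659 without T. bernacchii replicate 1) and KLF1_HUMAN lower (log2 fold change -3.49, SE 0.61, adjusted p = 0.00187). For heme synthesis, not called, 8 of 15 tested members were higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 1.58 and camera's adjusted p = 0.0988, or adjusted p = 0.856 with an estimated correlation. Higher ones numbered 5 without T. bernacchii replicate 1. That list passed at an adjusted p of 0.0314 without C. hamatus replicate 1, 0.0323 without C. hamatus replicate 3, 0.0433 without G. acuticeps replicate 1 and 0.0428 without G. acuticeps replicate 2. Other lists gained a call: the cell cycle (0.108 with all, 0.0235 without C. hamatus replicate 1, 0.0493 without C. hamatus replicate 2, 0.0323 without C. hamatus replicate 3, 0.0310 without G. acuticeps replicate 1 and 0.0402 without T. bernacchii replicate 1), the proteasome (0.123 with all, 0.0255 without G. acuticeps replicate 1) and T cells (0.108 with all, 0.0250 without G. acuticeps replicate 2). FIBB_HUMAN was at least 1891-fold lower in G. acuticeps than in T. bernacchii, or 1206-fold without T. bernacchii replicate 3.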

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

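The alternatives limited to rows counted in every species, rows of 1 mnemonic summed and C. hamatus replicate 1 alone were chosen after seeing the data. The 5 counts of differing rows stayed within 1.5 times their value under other scaling, other filters, DESeq2, glmTreat and each library left out, as did the 3 counts of pairs with each pair fitted alone. Leaving out 1 library gave 2665 to 4177 rows for C. hamatus against G. acuticeps, 2220 to 3508 against T. bernacchii, 2945 to 4274 against the mean, 1838 to 3090 for G. acuticeps against T. bernacchii, 1240 to 2015 the same way, and 5 to 11 lists, 5 without C. hamatus replicate 2. With 1 C. hamatus library, its spread is assumed to be that of the other groups. Without C. hamatus replicates 2 and 3, 2247 rows differed from G. acuticeps, 1780 from T. bernacchii, 2041 from the mean and 875 the same way, and 5 lists passed; fewer libraries lower the power, and the cause was not tested further. With rows counted in every species only, 1014 differed the same way, where fewer rows were tested. With an estimated correlation 0 of 25 lists passed camera, with 2 at an unadjusted p under 0.05, while fry passed 7 and the preset correlation 8. TGF-beta and BMP signalling, at camera's adjusted p of 0.0516, had 0.0404 with no filter, 0.0224 with the replicate block, 0.0344 with rows summed and 0.634 with an estimated correlation. The adjusted p of fry was 0.00166. That test asks whether a list changed at all, while camera compares it with the other rows, so the values of the tests answer different questions. Globins, at camera's adjusted p of 0.172, had 0.000213 with rows summed, and by fry, against no change, 0.00335.

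Of the 163 results for single genes, -1.13 for CP11A_ONCMY without C. hamatus replicate 3 was the one changed sign under the alternatives run for genes and chosen beforehand (DESeq2, its size factors, no filter, the replicate block and each library left out); its values without 1 library ran from -1.13 to 6.57. Without C. hamatus replicates 2 and 3, 1 C. hamatus library was left, and 6 of the 163 results changed sign. These were CP11A_ONCMY (-1.51), SCRB1_PIG (-0.36), PAI1_PIG (-1.06), CP17A_ICTPU, PNMT_PIG and TY3H_ANGAN. The last 3 are listed at 0 in replicate 1, so their fitted values of -4.53, -9.19 and -7.37 are no bounds. The cause was not tested. DESeq2 gave no adjusted p for 12 of these results, over 10 genes, and called the other 151.

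Pairing of libraries by number was not general. Correlations of deviations from the species means ran from -0.201 to 0.245 for libraries of the same number and from -0.160 to 0.212 for others. The highest was between C. hamatus replicate 2 and T. bernacchii replicate 2, and 3 of 9 libraries correlated best with their own number. With the replicate block, 3571, 2794, 2587, 3502 and 1517 rows differed, in the order C. hamatus against G. acuticeps and against T. bernacchii, G. acuticeps against T. bernacchii, C. hamatus against the mean, and the same way, and 10 lists passed. What depth alone limits was not tested. At the depth and spread of these libraries, simulation recovered 2% to 4% of rows changed 2-fold. It changed 200 of 8662 rows, while 2721 to 3636 were called in the data. Its adjusted threshold was therefore stricter, and these shares are not the power of the real comparisons.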

Other observations

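The tests of rows at 0 in 1 species and the splits of single lists were chosen after the result was seen; the other tests were chosen before. The 20 rows with the highest mean share of the counts included immunoglobulin light chains, globins, actins and ribosomal proteins. KACB_RAT, an immunoglobulin kappa region, held 5.97% of the counts of C. hamatus replicate 1, IGKC_MOUSE 2.28% of replicate 2, and KV401_HUMAN, a kappa variable region, 8.66% and 7.60% of T. bernacchii replicates 1 and 3. Entries of 1 protein from different organisms went opposite ways between species. RL5_CHICK was at least 557-fold lower in C. hamatus than in T. bernacchii, while RL5A_XENLA, the same ribosomal protein, stood at 5009 ± 3371 CPM in C. hamatus and 1.17 ± 1.25 in T. bernacchii. The sodium pump row AT1A1_ANGAN stood at 0.529 ± 0.917 CPM in C. hamatus and 74.1 ± 15.99 in G. acuticeps, and AT1A1_OREMO was at least 373-fold higher than in G. acuticeps.

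Such pairs raise the hypothesis that reads of 1 protein were assigned to different entries in different species. In all, 757 times a row was at 0 in every library of a species with a mean count of at least 100 in another. Of these, 59 (7.79%) had another row of the same mnemonic at a mean of at least 100 in the species at 0, against 5.54% of the other rows of that abundance (Fisher's exact test, two-sided, p = 0.0122). A row can enter that test once per species, and rows of 1 mnemonic depend on each other. The test takes its units as independent, so its p may be too small. Split assignment may therefore account for some of these rows, though by this measure a small part; entries of different mnemonics were not tested. Loss of genes in C. hamatus alone is argued against only as the source of these rows as a whole: 266 lay at 0 in C. hamatus, 295 in G. acuticeps and 196 in T. bernacchii. Whether some of the 266 rows are genes lost in C. hamatus was not tested. Assignment of reads to proteins of distant species remains open for the rest.

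The low median of the erythroid lists (heme synthesis, regulators and membrane, 59 tested members, called or not, -1.41 against the mean) could come from the table rather than the tissue, and the tests cover only narrow forms of this. Over the 55 members counted in every species the median was -1.46 (95% interval -2.49 to -0.39). With rows of 1 mnemonic summed it was -1.45 (-2.67 to -0.44). Both settings left 55 members, so the median could change little. They show only that the median did not rest on the few members left out or merged, and they weigh neither cause further. Rows with a few counts, and reads split between different mnemonics, were not tested. Leaving out the 20 highest rows and rescaling gave -1.45 (-2.70 to -0.35), with no member removed. This shows only that rescaling without these 20 rows left the median near its value. With no member removed, it cannot decide whether abundant rows set the median, and other abundant rows were not tested. The 111 members of the other blood cell lists had a median of 0.69, above the erythroid one by 0.64 to 3.16. Pooled, these lists did not fall with the erythroid ones. That interval covers the spread over members, not over libraries, and these lists did not move together. The stem and progenitor sum was 559 to 1224 CPM in C. hamatus, 1901 to 3101 in G. acuticeps and 823 to 1084 in T. bernacchii. A lower share of blood-forming cells is therefore not excluded. Fewer erythroid cells or less transcription per cell, a species difference the design names, also stay open and untested, along with the composition of the dissected tissue.

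The median of the TGF-beta and BMP list (59 tested members, 28 of them called higher) was 1.30. Over the 52 members counted in every species it was 0.88 (0.21 to 1.57), and with rows of 1 mnemonic summed 1.27 (0.39 to 1.79). The median thus fell when rows at 0 in a species were left out, but stayed above 0. Few members were left out or merged, so neither setting can decide what set the median. Leaving out the 20 highest rows and rescaling gave 1.24 (0.55 to 1.77), with no member removed. Here too this shows only that rescaling left the median near its value, and it cannot decide the question. More stroma in the C. hamatus tissue stays open: the 28 stroma and vessel members outside the list had a median of 1.71 (0.50 to 3.0), at least as high, led by CO6A1_MOUSE at 701 ± 181 CPM in C. hamatus. A change in signalling and a change in tissue composition cannot be separated by these values, and no sorting was described in the labels.

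Other splits of the libraries were counted. For each pair of species, the real split was 1 of 10 and the highest other count was 0, against 3636, 2810 and 2721; 10 splits are too few for a share under 0.05. For C. hamatus against the mean, 1 of 100 splits, the real one, gave as many as 3535 rows, and the highest other gave 1656. For rows the same way, 1 of 100 gave as many as 1559, and the highest other gave 814. These counts show only that the species of the 9 libraries matters. Mixing species within a group can widen the fitted spread, and 90 and 97 of 100 gave 0 rows. The split with 1656 and 814 rows kept all 3 G. acuticeps libraries as the first group. The real split was thus favoured from the start, and this comparison cannot exclude chance. Nor can chance be excluded for the number of lists past camera's threshold: 31 of 100 splits gave 8 or more, the highest other 14. By list, a camera p as small was reached in 3 of 100 splits for heme synthesis, 5 for erythroid regulators, 9 for hypoxia and vessel growth, 12 for the cell cycle, 16 for stroma and vessels, 21 for TGF-beta and BMP signalling, 31 for skeletal muscle, 36 for globins, 39 for the respiratory chain and 48 for the proteasome. Other splits mix the species, so real differences between them remain in those counts. Because each contrast shares the C. hamatus libraries, part of the excess of rows the same way over independence stays untested.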
